A study of Mus musculus with 4 samples.

How the data were processed

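Neutrophils were taken from tumors and blood of 3 FVB mice (an inbred mouse strain) that carried tumors grown from injected Py7160 cells, a mouse mammary tumor cell line. Per the labels' protocols, tumors of about 1 cm diameter were collected 2 to 3 weeks after injection and digested with enzymes, whereas blood went through red-cell lysis. Cells were then enriched through the surface protein Ly6G to about 90% purity and sorted on CD11b and Ly6G to over 99% purity. Each mouse was stained with its own hashtag antibody, an antibody carrying a DNA tag, and the 3 mice of a tissue were pooled and run as 1 Drop-seq library, a droplet method that captures single cells on barcoded beads. Each tissue therefore has 1 RNA library and 1 hashtag library. Tissue, library and the way cells were released are confounded throughout, and the tests measure the spread between mice within a library.

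The authors deposited raw UMI counts (counts of unique RNA molecules) per gene and cell barcode, and raw hashtag counts per barcode. The values are whole numbers with totals that differ between barcodes. STAR and the mouse genome build mm10 are named in the submitters' processing notes without versions. The gene counter, its annotation and any filter on barcodes are not given in the sources used here, so reads shared between near-identical genes, such as the hemoglobin genes Hbb-bs and Hbb-bt or Hba-a1 and its copy, may have been split or dropped in an unknown way. The tumor RNA file lists 15901 genes and 10000 barcodes with 1315437 UMIs, and the blood file 15236 genes and 10000 barcodes with 1969947 UMIs. The files share 12243 of 18894 genes, and a gene listed in a single file was given 0 counts in the other. Of the barcodes, 6383 in tumor and 6506 in blood also occur in the hashtag files, which hold 5277381 and 6050054 hashtag counts.

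Barcodes with at least 200 detected genes were kept, 963 in tumor and 1541 in blood, of which 959 and 1536 had hashtag counts. Mice were assigned with HTODemux of Seurat 5.3.0 (4 k-means centres, positive quantile 0.99). In tumor 134, 243 and 213 barcodes were assigned to mice 1, 2 and 3, 135 carried several hashtags and were dropped as doublets, and 234 had no call. In blood 478, 405 and 382 barcodes were assigned, 226 carried several hashtags and 45 had none. The tumor assignment depends on the rule. With at least 10 hashtag counts and at least 70% of them from a single hashtag, an alternative, mice 1, 2 and 3 held 106, 564 and 171 tumor cells. No other doublet caller was run, and doublets of cells from the same mouse are not seen by hashtags. A limit of 15% mitochondrial counts left 590 tumor and 1260 blood cells. UMIs were summed per mouse and tissue, giving 84533, 181818 and 141252 for tumor and 404297, 318692 and 297709 for blood. The median per cell lay between 551 and 668 UMIs in the tumor mice and between 638 and 672.5 in the blood mice. Precision is thus lowest in tumor mouse 1.

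Genes were compared between the 3 tumor and 3 blood sums with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), after its default low-count filter and TMM scaling, with tissue as the only term and Benjamini-Hochberg adjustment at 0.05. After the filter, 2916 genes with 91.7% of the counts were tested. Levels are given as CPM, the UMIs of a gene scaled to a common library total, mean ± SD of 3 mice. Where a tissue had 0 counts of a gene, the fold is a lower bound against 3 counts over the summed mice of that tissue. With 1 to 3 counts, the ratio of summed CPM is given with an exact 95% interval, which covers counting error only. The list tests used camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over 25 lists, and the estimated correlation and fry as alternatives. On simulated counts with this depth, run on 2658 genes, edgeR recovered 58 of 90 genes changed 2-fold (64.4%) and 84 of 85 changed 4-fold (98.8%), and called 8 of 2483 unchanged genes (0.322%). In the simulated list test the moved list was called, and 0 of 24 unmoved lists were. Simulated genes were drawn independently, so this does not test how the list calls hold up under correlation between genes. The simulations also changed fewer genes than were called between the tissues.

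The share of cells with an Acod1 UMI was compared after thinning each cell to 467 UMIs, the 25th percentile of the shallower tissue, which left out 147 tumor and 289 blood cells, with an exact two-sided permutation test of 3 against 3 mice. The number of random draws for thinning had not been fixed in advance. A draw from a single random stream gave 60.3% ± 1.82 in tumor and 0.546% ± 0.436 in blood. A draw with a seed for each cell then gave 57.3% ± 6.76 and 0.538% ± 0.238. After these had been seen, the exact expected share over all possible draws was adopted, and it is the value reported. Tumor cells with and without an Acod1 UMI in a thinned draw were compared in the same way with the mouse as a block, with Acod1 itself left out. Because single draws gave different calls, 10 draws were run, again a choice made after results had been seen.

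The design, the gene lists, the cell type markers and the rule for named genes were fixed before the data were examined. The rule names Acod1, Gpx4, Slc7a11, Nfe2l2, Csf2rb, Cebpb, S100a8 and S100a9. It adds the 10 higher and 10 lower genes with the largest fitted change among called genes with at least 100 CPM in the higher tissue and no overlap between mice, leaving out unnamed gene models, mitochondrial and ribosomal protein genes. It further adds up to 4 members of each list with the smallest p and any member whose direction is stated. Of 606 list members 597 were matched to the files' symbols, 3 of them under another symbol. Cells holding at least 3 UMIs over at least 2 markers of another type were counted as carrying its markers. Barcodes with 20 to 60 UMIs served as a measure of RNA outside cells, with markers of types that no tumor cell carried as a reference for its amount in cells. That reference was added after the results had been seen, in place of the Acod1 level ratio alone, which mitochondrial RNA in those barcodes affects. Gene positions are from GENCODE release M21 on mm10, 1-based. Alternatives were other size factors, DESeq2 1.42.0, other low-count filters, the replicate block, each mouse left out, other hashtag rules, other cell filters and thinning. Those added after seeing the data removed cells with macrophage or MHC class II genes, cells with markers of other types except erythroid ones, cells without neutrophil markers, or hemoglobin and mitochondrial rRNA genes, and varied the thinning draw. The removal of cells without neutrophil markers was run only within the tumor, not between the tissues. Python 3.11.15 with scipy 1.17.1 was used for the cell counts and exact tests.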

Results

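Drop-seq profiles were obtained from neutrophils of tumors and of blood of 3 mice bearing Py7160 mammary tumors, with the mice told apart by hashtags. The series concerns aconitate decarboxylase 1 (Acod1), the enzyme that makes itaconate from the TCA cycle intermediate cis-aconitate, and ferroptosis, an iron-dependent form of cell death by lipid peroxidation. After assignment to mice, 590 tumor cells with 407603 UMIs and 1260 blood cells with 1020698 UMIs were compared, with n = 3 mice per tissue and 1 library per tissue.

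Acod1 was among the genes that differed most between the tissues. It stood at 3221 ± 169 CPM in tumor neutrophils and 10.3 ± 4.67 CPM in blood neutrophils (SD, n = 3 mice each). The log2 fold change was 8.31 (edgeR, adjusted p = 1.13e-19) and rested on 1327 UMIs in tumor and 10 in blood. With each mouse and tissue sum left out in turn it ran from 7.84 to 8.42. At 467 UMIs per cell, 59.1% ± 2.25 of tumor cells and 0.339% ± 0.225 of blood cells held an Acod1 UMI (SD, n = 3). All tumor mice lay above all blood mice, with an exact permutation p of 0.1, the smallest that 3 against 3 mice allow. Without thinning, 368 of 590 tumor cells and 8 of 1260 blood cells held one, 62.4% and 0.635% of the pooled cells. In the 53 tumor cells with at least 500 genes, the share at 467 UMIs was 43.1% ± 10.9, against 0.289% ± 0.253 in blood. The tumor library held no group of cells that should lack Acod1, so RNA outside cells serves in its place. A cell made up wholly of the RNA in tumor barcodes with 20 to 60 UMIs would hold an Acod1 UMI at 467 UMIs in 60.8% of cases, no less than the share seen, so a UMI does not mark a single cell as expressing Acod1. Markers of 10 cell types that no tumor cell carried were together lower in cells than in those barcodes (ratio 0.275, 51 against 122 UMIs). At that ratio such RNA would give 22.7% of cells a UMI. This share is not a measured amount, since the types were picked for their absence from cells and their ratios differed. T cell markers stood at 31.9 CPM in cells and 14.9 CPM in those barcodes, and B cell markers at 17.2 and 149 CPM. Tumor barcodes with 20 to 60 UMIs held Acod1 at 2004 CPM (95% Poisson interval 1838 to 2180), against 3256 CPM (3083 to 3436) in the summed tumor cells and 2085 CPM (1776 to 2431) in those with at least 500 genes. The corresponding blood barcodes held 1 UMI in 246931. Acod1 lies on chromosome 14 at 103046977 to 103056573, plus strand, and is annotated as protein coding.

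**Figure D1:**
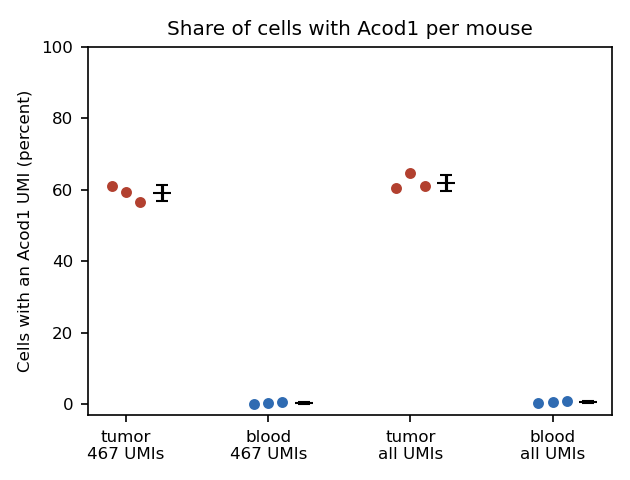
Percent of cells with at least 1 Acod1 UMI in tumor (red) and blood (blue) neutrophils, 1 point per mouse, at 467 UMIs per cell (expected share over all draws) and with all UMIs. The black mark and bar give the mean and SD of 3 mice, 59.1% ± 2.25 in tumor against 0.339% ± 0.225 in blood at 467 UMIs.

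Across the transcriptome, 908 genes were higher and 939 lower in tumor neutrophils among 2916 tested (edgeR, adjusted p under 0.05), and 746 and 758 of them by over 1 on the log2 scale. The mice of the tissues did not overlap for 1951 genes (66.9%), where chance gives 10%. The 10 largest fitted increases under the naming rule include several chemokine genes. Ccl3, a chemokine, stood at 7430 ± 1096 CPM in tumor and had 3 counts in blood, a ratio of 2564 (95% interval 877 to 12441). The neutrophil-attracting chemokine Cxcl2 rose from 21.2 ± 3.10 to 34782 ± 5982 CPM, a log2 fold change of 10.65. Ccl4 had a ratio of 1664 (568 to 8074), Hilpda, a lipid droplet protein induced by hypoxia, of 2086 (373 to 82488), and the prostaglandin synthase gene Ptgs2 of 711 (127 to 28188). Nr4a3, Cxcl1, Il23a, Cxcl3 and Plk3 had 0 counts in blood and were at least 237-fold, 189-fold, 135-fold, 113-fold and 76.0-fold higher in tumor. The largest decreases were in hemoglobin genes, with 0 counts in tumor: Hbb-bs was at least 1275-fold, Hba-a1 at least 825-fold and Hbb-bt at least 268-fold lower. Erythroid markers stood at 17475 CPM in blood cells, and higher, at 53537 CPM, in the blood barcodes used to measure RNA outside cells. The hemoglobin folds are therefore not read as lower expression in tumor neutrophils. After the hemoglobin genes came Slc35a5, Tnfaip8l2, AI467606, Gsdme, D1Ertd622e, Cep19 and Asb7, each with 1 to 3 counts in tumor. Their blood over tumor ratios ran from 30.0 (10.1 to 146) for Cep19 to 64.3 (11.4 to 2555) for Slc35a5.

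Among the other genes named in advance, Slc7a11, the cystine transporter that feeds glutathione synthesis, rose from 18.2 ± 5.60 to 598.6 ± 15.04 CPM. Its log2 fold change of 5.06 rested on 18 UMIs in blood and 244 in tumor. With each sum left out in turn it ran from 4.74 to 5.16. Nfe2l2, which encodes the oxidative stress regulator Nrf2, rose by 1.30 on the log2 scale, from 400 ± 38.0 to 959 ± 165 CPM. Cebpb, a transcription factor of emergency granulopoiesis, rose from 90.9 ± 19.95 to 2039 ± 268 CPM, by 4.47. The calprotectin genes S100a8 and S100a9, the most abundant neutrophil transcripts in blood, fell by 1.46 and 1.34. S100a8 stood at 31336 ± 4109 CPM in tumor and 87761 ± 8397 CPM in blood. Csf2rb, the shared receptor chain for GM-CSF, stood at 395 ± 103 and 370 ± 57.3 CPM (log2 fold change 0.17, edgeR adjusted p = 0.408), and its sign changed in 3 of the alternatives. Gpx4, the glutathione peroxidase that removes lipid peroxides, had 11 UMIs in tumor and 36 in blood and was dropped by the low-count filter. In the fit without that filter its log2 fold change was −0.70 (edgeR adjusted p = 0.476), so a difference was not detectable at this depth. An interval derived from the test's F statistic ran from −1.78 to 0.38.

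**Figure D2:**
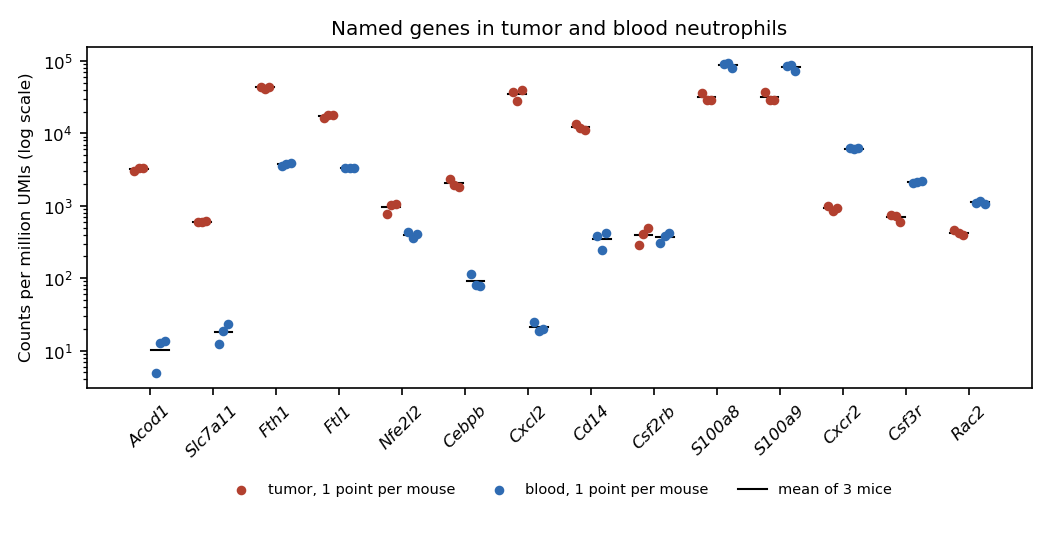
Level in CPM on a log axis for 14 genes in tumor (red) and blood (blue) neutrophils, 1 point per mouse, with the mean of 3 mice as a black line. Acod1 stood at 3221 CPM in tumor and 10.3 in blood, while Csf2rb overlapped between the tissues at 395 and 370 CPM.

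The ferroptosis defence list, which includes the ferritin genes, was higher in tumor neutrophils. Of 12 tested members of the defence list 8 rose and 2 fell, with a median log2 fold change of 2.50 (camera adjusted p = 0.00665; adjusted p = 0.162 with an estimated correlation). Without the low-count filter 9 of 23 members rose and 2 fell, with a median of 1.59. The ferritin chains Fth1 and Ftl1 rose by 3.56 and 2.42, Fth1 from 3741 ± 224 to 43118 ± 1483 CPM. Txnrd1, thioredoxin reductase, rose by 2.91, and Slc3a2, the partner chain of Slc7a11, by 4.39. The iron exporter Slc40a1 and glutathione reductase Gsr fell by 1.89 and 1.39. Of 7 members of the promotion list, Por and Sat1 rose and Alox5ap, Cyb5r1 and Alox5 fell (median −0.44, camera adjusted p = 0.765). Without the low-count filter 3 of 21 members rose and 5 fell, with a median of 0.35. Among the 3 were Acsl4, which builds peroxidation-prone phospholipids (25 and 12 UMIs in tumor and blood, log2 fold change 2.02, edgeR adjusted p = 0.00292), and the transferrin receptor gene Tfrc (18 and 4 UMIs, 3.04, edgeR adjusted p = 8.51e-04). Of 20 members of the Nrf2 list 13 rose and 5 fell, with a median of 1.44 (camera adjusted p = 0.0141; adjusted p = 0.308 with an estimated correlation). The Nrf2 call was lost without cells carrying markers of another type (camera adjusted p = 0.0667) and after thinning (0.0673), with fewer members tested. In this list Sqstm1 rose by 3.30 and the heme oxygenase gene Hmox1 by 2.12. Apart from Gsr, the members that fell encode enzymes of the pentose phosphate pathway, G6pdx (−3.12), Pgd (−2.38), Taldo1 (−1.50) and Tkt (−1.43). The iron list had 5 risen and 3 fallen of 12, among the latter the metalloreductase Steap4 (−2.31), with a median of 0.36 (camera adjusted p = 0.583). The glutathione and thioredoxin list had 6 risen and 6 fallen of 14 (median 0.19, camera adjusted p = 0.620), with Sod2 up by 3.55 and Gpx1 and Msrb1 down by 2.03 and 1.34.

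Glycolysis and hypoxia genes were higher in tumor neutrophils, although the glycolysis call was lost after thinning (camera adjusted p = 0.0673, fewer members tested). Of 16 glycolysis members 12 rose and 3 fell over all genes, and 13 rose adjusted over the list alone, with a median of 1.29 (camera adjusted p = 0.00665; adjusted p = 0.247 with an estimated correlation). Tpi1, Hk2, Ldha and Pfkl rose by 3.64, 3.49, 1.68 and 4.62, whereas Pfkfb4, Slc2a3 and Gpi1 fell by 2.83, 1.13 and 0.80. Of 16 hypoxia members 14 rose and 0 fell, with a median of 2.69 (camera adjusted p = 8.39e-06; adjusted p = 0.0524 with an estimated correlation). Besides Hilpda these included Plin2, a lipid droplet coat protein (3.79), Ero1l (5.94), the cytokine Mif (3.99) and Hif1a itself (1.69). Only 5 members of the TCA cycle and itaconate list were tested. Apart from Acod1, Sdhd fell by 0.98 and 3 did not pass, and the list's median of −0.07 differed in sign from its mean of 1.41 and its test (Up, camera adjusted p = 0.752). Of 31 oxidative phosphorylation genes 6 rose and 2 fell, or 2 and 1 adjusted over the list alone (median 0.20, camera adjusted p = 0.620), and without the low-count filter 1 of 51 rose and 5 fell (median −0.17). Ndufs8 rose by 1.85 and Cox6c fell by 1.00. Among all 25 lists, 23 had the same counts adjusted over the list alone as over all genes.

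The NF-kB and cytokine list had the smallest p of the 25 lists. Of 36 tested NF-kB and cytokine genes 32 rose and 0 fell, with a median of 3.89 (camera adjusted p = 4.26e-14), also with 5 members that had 0 counts in blood set at their bound. This was the only one of the 10 called lists that kept its call with an estimated correlation (adjusted p = 0.0187). Besides Cxcl2, Ccl3 and Ccl4, the chemerin receptor gene Ccrl2 rose by 8.36, the NF-kB inhibitor gene Nfkbia by 4.90 and Tnf by 6.68. The list of tumor neutrophil state, drawn from textbook knowledge, had 15 risen and 2 fallen of 18 (median 4.25, camera adjusted p = 7.86e-07; adjusted p = 0.0524 with an estimated correlation). Cd14, a lipopolysaccharide co-receptor, rose by 5.15, while Xbp1 and Gngt2 fell by 1.36 and 0.52. Of 21 immediate early and heat shock genes, which also respond to tissue dissociation, 18 rose and 1 fell (median 1.55, camera adjusted p = 2.12e-05; adjusted p = 0.247 with an estimated correlation), with Ier3 up by 4.12, Hsp90aa1 by 3.84 and Nr4a1 by 5.42, and Ier2 down by 0.99. Egr1, an early growth response factor, had 3 counts in blood and a ratio of 289 (98.0 to 1407). Of 13 genes of the unfolded protein and integrated stress responses 10 rose and 2 fell (median 1.74, camera adjusted p = 0.00593; adjusted p = 0.325 with an estimated correlation). Ppp1r15a, Hspa5, Dnajb9 and Atf3 rose by 5.31, 2.71, 4.88 and 5.45.

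Secondary and tertiary granule genes were lower in the tumor cells assigned to mice, whereas the list of surface and migration receptors was not called. Of 19 secondary and tertiary granule genes 13 fell and 2 rose, with a median of −1.98 (camera adjusted p = 0.00590; adjusted p = 0.387 with an estimated correlation). Hp, Anxa1, Pglyrp1 and Mmp9 fell by 2.15, 2.35, 2.38 and 2.30, whereas Olfm4 and Adam8 rose by 2.38 and 1.02. Without cells holding macrophage or MHC class II genes the median was −0.82 over 16 members and the call was lost (camera adjusted p = 0.0840). That alternative removed blood cells too, leaving 1119 of 1260. In blood, Ly6c2 held 324 of the 630 UMIs of the monocyte or macrophage markers it counts. The lost call is therefore not read as an effect of macrophages. Tumor barcodes without a hashtag call, which like the other classes named here entered no comparison, differed from the assigned cells: the list members Camp and Ngp, antimicrobial granule genes, stood at 4114 and 5349 CPM there, at 2643 and 1888 CPM in those with several hashtags and at 32.6 and 136 CPM in those with at least 100 but under 200 genes, against 326 and 832 CPM in the summed assigned tumor cells and 2924 and 2887 CPM in blood cells. Neither gene passed the test between tissues. No list test was rerun under another hashtag rule, although the 70% rule assigned 564 cells, in place of 243, to tumor mouse 2. The granule result thus holds for the cells assigned by the main rule only. Of 20 surface and migration receptors 12 fell and 4 rose (median −0.91, camera adjusted p = 0.0896). The chemokine receptor Cxcr2 fell from 6154 ± 68.1 to 929 ± 71.4 CPM, and Selplg, Csf3r and Ly6g, the gene of the sorted surface protein, fell by 2.37, 1.61 and 2.93. Trem1, Ptafr, Cxcr1 and Ccr1 rose. The marker list of immature neutrophils, which includes Camp and Ngp, stood at 1626 ± 1161 CPM in tumor and 6674 ± 3811 CPM in blood. Ngp held 339 of its 559 tumor UMIs and Camp 2985 of its 6988 blood UMIs. Its member Mpo had 0 UMIs in both tissues, so the list mostly restates granule genes. The only primary granule gene tested, Cd63, rose by 3.06 (list test adjusted p = 0.244). Of 8 genes of aged neutrophils 4 rose and 1 fell (median 1.08, camera adjusted p = 0.0745), the risen ones being Cd274 (the gene of PD-L1), Icam1, Cd63 and Cxcr4. Of 10 NADPH oxidase genes 3 fell and 0 rose (median −0.36, camera adjusted p = 0.294), among them Rac2 and Cyba, by 1.37 and 0.48.

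**Figure D3:**
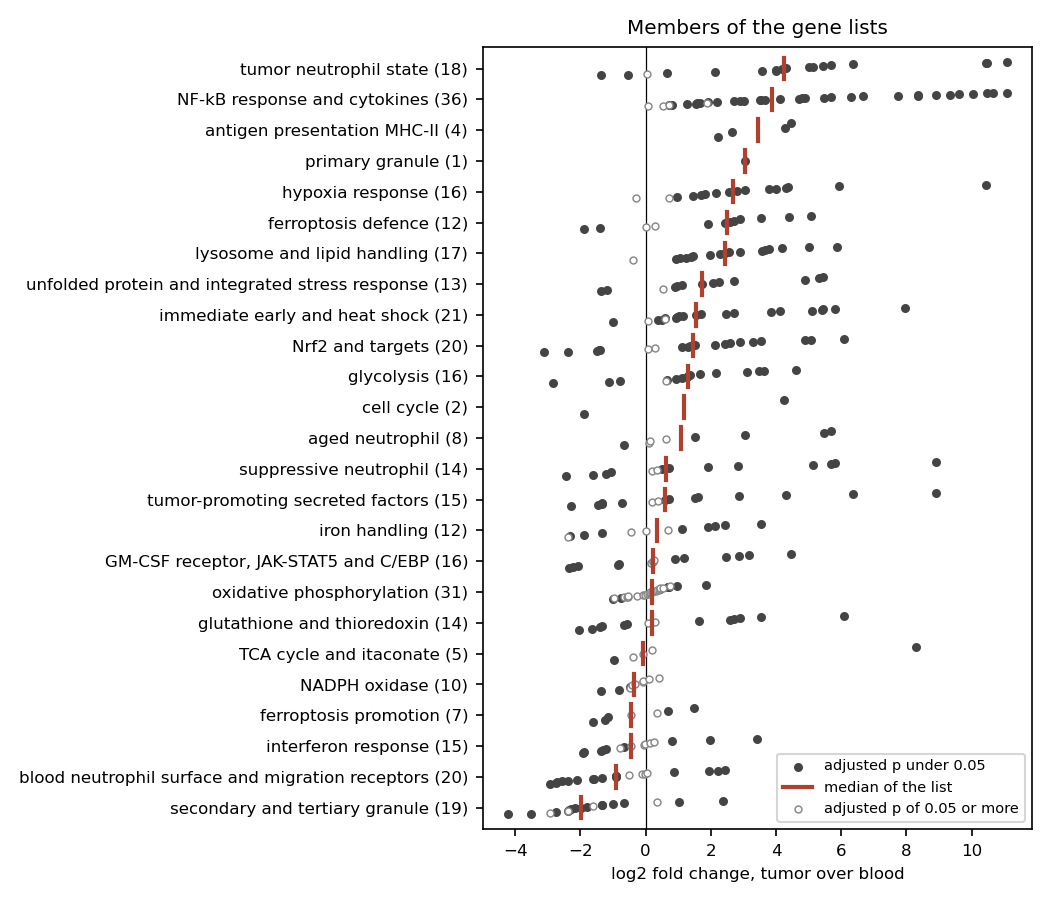
Fitted log2 fold change, tumor over blood, of each tested member of 25 gene lists (number tested in brackets). Filled points passed the test, open points did not, and the red line is the list's median, from 4.25 for tumor neutrophil state to −1.98 for secondary and tertiary granule genes.

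Further immune lists went both ways. Of 14 genes linked to suppressive neutrophils 8 rose and 4 fell (median 0.62, camera adjusted p = 0.0982), with Clec4e and Clec4d up by 2.83 and 1.91 and Wfdc17, Ifitm1, Myd88 and Cd84 down by 1.60, 1.22, 2.43 and 1.05. The list of GM-CSF receptor, JAK-STAT5 and C/EBP genes had 6 risen and 5 fallen of 16 (median 0.24, camera adjusted p = 0.406). Pim1 and Osm rose by 2.47 and 2.87, and Cebpd and Stat5b fell by 2.35 and 2.06. Of 15 interferon genes 3 rose and 6 fell (median −0.45, camera adjusted p = 0.362), Rsad2 and Isg15 rising by 3.41 and 1.97 and Slfn1 and Trim30a falling by 1.90 and 1.93. Of 15 tumor-promoting secreted factors 8 rose and 5 fell (median 0.58, camera adjusted p = 0.294). Vegfa rose by 4.32, and Spp1 (osteopontin) had a tumor over blood ratio of 96.0 (32.0 to 472). Of the 2 cell cycle genes tested, Pcna rose by 4.25 and Hmgb2 fell by 1.88 (camera adjusted p = 0.861).

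Lysosomal and lipid genes were higher in the sorted tumor cells, and so were the 4 tested genes of MHC class II presentation, whose list was not called. Of 17 lysosome and lipid genes 16 rose and 0 fell (median 2.45, camera adjusted p = 9.90e-06; adjusted p = 0.0716 with an estimated correlation). The protease inhibitor gene Cstb and the cathepsin genes Ctsb and Ctsz rose by 5.02, 3.57 and 3.68. All 4 tested presentation genes rose (median 3.46, camera adjusted p = 0.0745), the co-stimulatory genes Cd80 and Cd86 by 2.66 and 2.21, and H2-Aa and Cd74 by 4.45 and 4.27. Of the tumor cells, 16 (2.71%, exact 95% interval 1.56 to 4.37) carried monocyte or macrophage markers, 1, 9 and 6 in the mice, and these cells held 82.0% of the Cd74, 76.9% of the H2-Aa and 83.5% of the Apoe UMIs. Among lysosome genes they held 54.5% of the UMIs of the cathepsin gene Ctss but 4.18% of Ctsb and 1.78% of Cstb, with 5.51% of all UMIs. The edgeR call of Cd74 was lost on leaving out any of the 6 mouse and tissue sums except that of tumor mouse 1 (adjusted p up to 0.0807) and that of H2-Aa for 3 of 6 (up to 0.0604). The calls of Apoe and Ctss, up by 2.30 and 2.45, were lost in the same 5 of 6 cases (adjusted p up to 0.111 and 0.105). Apoe stood at a log2 fold change of 0.14 (edgeR adjusted p = 0.637) without cells carrying markers of other types except erythroid ones. Apoe is itself one of the markers that pick these cells. Its share in them and its fall on their removal thus follow in part from the selection.

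Few cells carried markers of another type apart from erythroid ones, by the rule of at least 3 UMIs over at least 2 markers. By the wider rule of at least 2 UMIs of monocyte, macrophage or MHC class II genes, used in the alternative that removes such cells, 58 of 590 tumor cells (9.83%) and 130 of 1260 blood cells (10.3%) were counted. Neutrophil markers were carried by 529 of 590 tumor cells (89.7%) and 1254 of 1260 blood cells (99.5%). T cell, B cell, NK cell, dendritic, epithelial, fibroblast, endothelial, platelet and mast cell markers were carried by 0 tumor cells each. Eosinophil markers were carried by 1. For a count of 0 the exact 95% interval reaches 0.623%. It covers the sampling of cells and not detection. Cells of a type that hold too few of its UMIs go uncounted, and 106 of 129 markers were in the files. In blood, T cell markers were carried by 11 cells, B cell by 3, NK cell by 1, platelet by 2, monocyte or macrophage by 15 and dendritic, epithelial, fibroblast, endothelial, mast cell and eosinophil markers by 0. Markers of the immature neutrophil list, which includes the granule genes Camp and Ngp, were carried by 6 tumor and 61 blood cells. Erythroid markers were carried by 463 blood cells (36.7%) and 0 tumor cells. Erythroid transcripts made up 17475 CPM of the blood cells and 53537 CPM of the blood barcodes with 20 to 60 UMIs.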

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

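The 4 tests of explanations in this part were chosen after the results they bear on had been seen. Acod1 was above its blood level in tumor barcodes that entered no comparison. It stood at 2627 CPM (95% Poisson interval 2360 to 2915) in 231 tumor barcodes with at least 200 genes, at most 15% mitochondrial counts and no hashtag call, at 2760 CPM (2460 to 3087) in 123 with several hashtags, at 3763 CPM (3488 to 4054) in 732 with at least 100 but under 200 genes, and at 2004 CPM in 5945 barcodes with 20 to 60 UMIs. Blood barcodes of these kinds held 0, 2, 4 and 1 Acod1 UMIs. The assigned tumor cells, at 3256 CPM (3083 to 3436), lay between these classes. In the 53 tumor cells with at least 500 genes Acod1 stood at 2085 CPM (1776 to 2431), an interval that overlaps the 1838 to 2180 of the barcodes with 20 to 60 UMIs. The 234 tumor barcodes without a call before the mitochondrial limit had a median of 97.1% of their hashtag counts in a single hashtag. In the 231 after it, the granule genes Camp and Ngp stood at 4114 and 5349 CPM, in those with several hashtags at 2643 and 1888 CPM and in those with at least 100 but under 200 genes at 32.6 and 136 CPM, against 326 and 832 CPM in the assigned tumor cells.

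The pattern weighed first is the higher Acod1 of tumor neutrophils. Without cells holding macrophage or MHC class II genes its log2 fold change was 9.04, not lower, which argues against monocytes or macrophages in the sort as the whole cause. Acod1 alone does not decide on RNA outside cells, since without mitochondrial genes, 33.9% of UMIs in tumor barcodes with 20 to 60 UMIs, it stood at 3362 CPM in cells and 3033 CPM in those barcodes, with overlapping intervals (3183 to 3547 and 2782 to 3301). Relative to markers of 10 cell types that no tumor cell carried, spread over 111 such barcodes, its cell to barcode ratio was 5.91 times theirs (interval 4.1998 to 8.32). Those types were picked for their absence from cells, which by itself can lower their ratio. The ratio also differed between them, T cell markers being higher in cells and B cell markers lower. The comparison therefore does not decide either, and RNA outside cells stays open and may add to the share of cells with a UMI. The immediate early and heat shock list, with a median log2 fold change of 1.55, was also higher in tumor, and with 1 library per tissue an effect of tissue dissociation or library cannot be told apart from a biological one of the tumor, which stays open and untested.

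Of the 10 splits of the 6 mouse and tissue sums into 3 and 3, the real split called 1847 genes and 1 split, the real one, gave as many, while the highest of the others called 0. Every other split mixes tumor and blood sums within a group, which puts the tissue difference into the spread and leaves few calls. With 10 splits the share also cannot fall to 0.05, so this comparison does not decide on chance.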

How the results depend on the processing

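The alternatives for macrophage or MHC class II genes, for markers of other types except erythroid ones, for neutrophil markers, for hemoglobin and mitochondrial rRNA genes, for thinning draws and for list medians without a low-count filter were chosen after seeing the data, as were a HTODemux quantile of 0.95 and no mitochondrial limit for the Acod1 share. The Acod1 log2 fold change passed under all 21 alternatives (7.78 to 9.04). The cause of a change was not tested unless named. Against 908 higher and 939 lower genes, 239 and 253 passed with at least 500 genes per cell (978 tested), 571 and 563 after thinning (1686 tested), both with fewer genes tested, and 1435 were lower without a low-count filter (15018 tested). With at least 500 genes per cell 23 genes called over all cells took the opposite sign, against 0 or 1 under each other alternative. Without that filter and with DESeq2 the median of all genes shifted by −0.32 and −0.14. Without it, and with more members, list medians turned to 0.35 (ferroptosis promotion), −0.17 (oxidative phosphorylation), −1.70 (primary granule, 6 members), −0.082 (GM-CSF) and −0.25 (glutathione), while those of the 10 called lists kept their sign. With the replicate block 886 genes were higher and 915 lower, and the MHC class II list was called (adjusted p = 0.0206), with no other list call changed. In their deviations from the tissue mean, same-numbered sums correlated at 0.07, −0.10 and −0.07, and only sums of mouse 1 correlated best with their own number in both tissues. With 3 sums per tissue this cannot settle whether a number marks the same mouse in both tissues, which the labels do not say. The main fit, without the block, may thus leave out a real pairing. The difference in Acod1 share, 58.8 points, was 61.4 without thinning and 42.8 with at least 500 genes per cell (53 tumor cells), and 56.8 to 60.7 over 10 single draws. Of 25 lists, 10 were called at the preset correlation, 1 with an estimated correlation and 22 by fry, which does not compare a list with other genes. Lists share members, such as Slc7a11 and Fth1 in ferroptosis defence and Nrf2, or Ccl3 and Ccl4 in tumor state and NF-kB. Their calls are thus not separate results. Estimated correlation gave adjusted p of 0.162 (ferroptosis defence), 0.308 (Nrf2), 0.247 (glycolysis), 0.0524 (hypoxia), 0.387 (secondary granule), 0.0524 (tumor state), 0.247 (immediate early), 0.325 (unfolded protein) and 0.0716 (lysosome). By fry further lists passed: iron 6.55e-05, TCA cycle 2.39e-04, oxidative phosphorylation 0.0405, NADPH oxidase 0.00990, primary granule 0.00181, migration receptors 0.00178, aged 1.71e-05, suppressive 3.05e-04, GM-CSF 6.45e-04, secreted factors 0.00211, MHC class II 0.00432 and glutathione 1.70e-04. Removing cells with markers of another type ended the Nrf2 call (0.0667, median 1.503 over 17 members, against 1.44 over 20), and thinning the Nrf2 and glycolysis calls (both 0.0673, medians 1.25 over 17 and 1.32 over 14, the latter against 1.29 over 16), with fewer members tested. Removing cells with macrophage or MHC class II genes ended the secondary granule call (0.0840) and moved its median from −1.98 over 19 members to −0.82 over 16. The direction of the oxidative phosphorylation test, not called, turned after thinning (0.920). With each sum left out in turn, adjusted p ran from 0.621 to 0.854 for ferroptosis promotion, whose direction turned on leaving out tumor mouse 1, 2 or 3. It ran from 0.0474 to 0.142 for migration receptors, called without tumor mouse 1, and from 0.00664 to 0.0798 for MHC class II, called on leaving out tumor mouse 1, 2 or 3. Of 2921 values of 143 named genes under alternatives, 2828 kept direction and side of the threshold, 80 lost the call, 8 gained it and 5 turned. Csf2rb turned to −0.16 without a low-count filter and ran from −0.029 to 0.33 over sums left out. Apoe turned to −0.10 without cells with markers of another type and −0.029 without cells with macrophage or MHC class II genes. As Apoe is a marker that picks the cells removed in both, these values follow in part from the selection. Over sums left out Apoe ran from 1.98 to 2.68, with its call lost in all cases but tumor mouse 1 (edgeR adjusted p up to 0.111). For tumor cells with and without Acod1, 14 genes were called in the first seeded draw, 7 without markers of another type, 5 with neutrophil markers only (0 to 13 over 10 draws), 1 to 27 over 10 draws of all cells and 24 in a single stream. Depth limits genes such as Gpx4, with 11 tumor UMIs.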

Other observations

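The tests on MHC class II and lysosome genes and on RNA outside cells were chosen after the results were seen. For cells with Acod1 the comparison itself was planned, but the removal of cells with macrophage or MHC class II genes or without neutrophil markers, the seeded draws and their number were chosen after data had been seen. Within the tumor, cells with and without an Acod1 UMI at 467 UMIs were compared in the 3 mice. The groups differ in a drawn UMI, which RNA outside cells can supply, and are not read as cell states. The NF-kB and cytokine list was higher in cells with Acod1, with a median log2 fold change of 0.40 (camera adjusted p = 6.84e-04; adjusted p = 0.898 with an estimated correlation), and no other of the 23 lists tested was called. In the first draw with a seed for each cell, adopted after the single stream had been seen, 11 genes were higher and 3 lower among 539 tested by edgeR. Ccl3, named after its values were seen, stood at 9792 ± 2073 CPM with and 4879 ± 2037 CPM without Acod1 and was called in 7 of 10 draws (5 of 10 with neutrophil markers only). Calls of single genes depended on the draw, from 1 to 27 genes.

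For this NF-kB pattern, removing cells with macrophage or MHC class II genes left the list called in 10 of 10 draws (adjusted p up to 0.0216; adjusted p = 0.884 with an estimated correlation in the first seeded draw), which at the preset correlation alone argues against monocytes or macrophages as the whole cause. With only cells holding neutrophil markers it was called in 8 of 10 draws (adjusted p 7.59e-04 to 0.0582; adjusted p = 0.829 with an estimated correlation in the first seeded draw), and in the first draw made, from a single random stream, it was not called there (adjusted p = 0.120, with 0 genes called). The rule that all draws must agree was set after these values were seen, so a contribution of cells without neutrophil markers stays open. RNA outside cells stays open too, since relative to 514 other tested genes the list's median log2 ratio of barcodes with 20 to 60 UMIs over cells was −0.20, with an interval from −0.64 to 0.36. No group of the design separates a biological explanation, and none was tested.

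For the higher MHC class II genes of the sorted tumor cells, cells with monocyte or macrophage markers held 80.1% of the Cd74 and H2-Aa UMIs. Without cells carrying markers of other types except erythroid ones, H2-Aa went from 234 to 54 UMIs in tumor, 41 of them in mouse 2, and from 25 to 0 in blood, so that it was still called (at least 45.7-fold, edgeR adjusted p = 0.00125). That call covers H2-Aa alone and not the other MHC class II genes. Cells with monocyte or macrophage markers thus hold most of the tumor UMIs of Cd74 and H2-Aa. Whether they cause the difference from blood stays open. The lysosome and lipid list was still called without the wider set of cells holding macrophage or MHC class II genes. Its median log2 fold change there was 2.04. At the preset correlation this argues against these cells as the whole cause, though they bear on the member Ctss. The member Apoe is one of the genes that pick these cells, so its fall does not bear on this. Over all cells the list's call was lost with an estimated correlation (camera adjusted p = 0.0716). Cd80 and Cd86 had 7.69% and 10.3% of their UMIs in cells with those markers, and tissue dissociation and library remain confounded with tumor for these lists.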
